A study of Mus musculus with 2 samples.

How the data were processed

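Nuclei were isolated from the dissected neocortices of mouse embryos, and their RNA was measured with the 10x Genomics 3' version 3 chemistry on an Illumina NovaSeq, per the labels' protocols. The 2 libraries carry the genotype labels MEN1-F/F and MEN1-NCKO. The embryonic age, the number of embryos pooled in each library and the part of Men1 that was targeted are not given in the sources used here. With 1 library per label there is no spread between replicates, so no test was run and values are given side by side.

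The deposited files hold whole-number UMI counts per gene and barcode, not normalized. They were made with Cell Ranger 6.1.0, per the file headers, and reads were aligned to the mouse build mm10, per the submitters' processing notes. These notes also name Seurat without a version or a role. The gene table lists 33938 genes, of which 32241 identifiers were found in GENCODE vM21, the annotation of the same assembly (GRCm38) used here for positions. The other 1697 have no position here, and 36 symbols occur on more than 1 line, of which the line with more UMIs was used for listed genes. The strandedness of the counting is not given in the sources used here, so a gene that overlaps a neighbour can share its UMIs.

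The files hold 6477 barcodes with 30116311 UMIs (F/F) and 10750 barcodes with 50115162 UMIs (NCKO). Barcodes with under 500 genes (10 and 19) or over 5% mitochondrial UMIs (1 and 0) were left out. Doublets were scored with a Python implementation of the Scrublet approach, with 2 simulated doublets per nucleus. The highest scores in each library were removed, 0.8% per 1000 deposited barcodes (336 and 924, of which 0 and 1 also had under 500 genes). Of 150 doublets made by adding pairs of F/F nuclei, 47.3% were among the highest scores when the number removed was raised by 150, with a median score of 0.791 against 0.330 for the nuclei.

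The 6130 and 9808 kept nuclei were scaled to 10000 UMIs and log-transformed. The 2000 most variable genes were chosen without cell cycle, sex-linked, mitochondrial and haemoglobin genes. They were reduced to 30 principal components, and a shared-neighbour graph of 20 neighbours was clustered jointly for both libraries with the Leiden algorithm at resolution 1 (scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). No difference between the libraries was removed before clustering.

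Marker genes of each class were fixed before the data were examined, and the rule that turns them into names was settled after the clusters and their shares per library had been seen. In this rule a class is given to a cluster when the mean log2 fold of its markers, against the mean of the other clusters, is the highest, is at least 0.5 and exceeds the next class by 0.1. At least 3 detected markers must be raised 1.5-fold. Clusters of at least 100 nuclei whose 2 best classes lay within 0.3 were first split once at resolution 0.5. A cluster was left unnamed when its 10 leading genes held more markers of another class than of its own, or when they held a gene pair that goes against every fixed name (Zbtb20 with Nrp2, or Tshz1 with Pbx3). The same was done when 3 times its median UMI count was under the median of all nuclei with none of its markers leading. Of 45 clusters, 33 were named and 12 were not. Earlier versions of the rule, without the split and with scores against all other nuclei, are among the alternatives.

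UMIs were summed per library and class and given as CPM, which scales the UMIs of a gene by all UMIs of that library and class, computed here from the deposited counts. Levels carry the exact Poisson 95% interval, ratios of levels the exact conditional binomial interval, shares of nuclei the exact Clopper-Pearson interval, and differences of shares Newcombe's interval built on it. All intervals cover counting error only. Gene ratios are log2 of (CPM + 5) in the NCKO-labelled library over (CPM + 5) in the F/F-labelled library, for genes with at least 50 UMIs in the class. The pseudocount draws the ratios of low genes towards 0. Classes with at least 100 nuclei in each library were compared, which gave 9 populations.

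For each of 28 gene lists fixed before the data were examined, the median log2 ratio of the measured members was set against 10000 random lists of the same size, drawn from 25 bins of mean expression. The percentile describes these libraries and is not a test. A list with under 3 members over the minimum was given no median. Shares of nuclei with a UMI of a cell cycle gene were compared after each nucleus was thinned to 1000 UMIs.

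Besides Men1, Epha4 and list members, the genes named were chosen by a rule of size. Among genes with at least 100 UMIs over both libraries in a population, the 12 highest and 12 lowest log2 ratios were taken in upper-layer and radial glia-like nuclei. In each other class with at least 200 nuclei per library, and over all kept nuclei, the 6 highest and 6 lowest were taken. Mitochondrial, haemoglobin, Xist, Tsix and Y-linked genes were left out. On simulated counts with 200 genes changed 2-fold, 24 of 24 genes named in upper-layer-like nuclei (9530 genes) and 24 of 24 in radial glia-like nuclei (2784 genes) were changed ones. The ratio intervals held the simulated value for 95.7% and 95.3% of the genes. Of 1000 simulated lists of unchanged genes, 6.20% and 4.30% lay outside the central 95% of random lists, and 50 of 50 lists of raised genes lay above it in each class. The simulated counts held counting error only. They check the calculation and say nothing about variation between nuclei, clusters, embryos or libraries.

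Alternatives were other filters on nuclei, no doublet removal, another scaling, other pseudocounts, no count minimum, other clustering resolutions, clusters drawn from the F/F-labelled library alone and equal depth per nucleus. Those chosen after the data were seen were centring of genes within each library, the other naming rules, the migrating and upper-layer classes combined, and the clusters of a class weighted as in the F/F-labelled library.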

Results

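Single-nucleus RNA-seq was carried out on embryonic mouse neocortex from 1 library labelled MEN1-F/F and 1 labelled MEN1-NCKO. The study's title names menin, the product of Men1, and the receptor EphA4 in late-born neurons. After filtering, 6130 F/F-labelled nuclei held 26815944 UMIs and 9808 NCKO-labelled nuclei held 41455483 UMIs. The median depth was 3669.5 and 3583.5 UMIs per nucleus, with 1843 and 1802 genes and 0.154% and 0.180% mitochondrial UMIs. The depth per nucleus thus differed little between the libraries, while the number of nuclei differed more. There is no replicate of either label, so each difference is between these 2 libraries.

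Over all nuclei, Men1 was not lower in the library labelled MEN1-NCKO. This gene encodes menin, a scaffold protein of MLL histone methyltransferase complexes, and lies on the plus strand of chromosome 19 from 6334979 to 6340891 (GRCm38, ENSMUSG00000024947). Over all kept nuclei it had 276 UMIs in the F/F-labelled library, 10.3 CPM (95% Poisson interval 9.11 to 11.6). The NCKO-labelled library had 563 UMIs, 13.6 CPM (12.5 to 14.8), a ratio of 1.32 (1.14 to 1.53), and at equal depth per nucleus the ratio was 1.08. In upper-layer-like nuclei the level was 11.9 against 18.3 CPM (ratio 1.53, 1.11 to 2.13). Radial glia-like nuclei had 12 UMIs (22.9 CPM) against 6 (8.04 CPM), a ratio of 0.351 with an interval from 0.108 to 1.01. Intermediate progenitor-like nuclei had 12 against 5 UMIs, a ratio of 0.513 (0.142 to 1.56). In layer 6-like nuclei the ratio of 1.65 (1.004 to 2.78), from 24 and 56 UMIs, became 0.853 at equal depth. That value rests on fewer UMIs still and carries no interval. The level of Men1 over all nuclei therefore does not bear out the label, but it cannot refute it either. Libraries are named by their labels throughout. The labels do not say which part of the gene was deleted, and a 3' tag outside the deleted part checks nothing.

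Epha4, a receptor tyrosine kinase that binds ephrins and acts in axon guidance and cell sorting, was lower in the NCKO-labelled library in all 9 populations compared. It lies on the minus strand of chromosome 1 from 77367185 to 77515088 (ENSMUSG00000026235). Over all nuclei its level was 254 CPM (248 to 260) in the F/F-labelled and 160 CPM (157 to 164) in the NCKO-labelled library, from 6819 and 6651 UMIs. The ratio of 0.631 (0.610 to 0.653) was at percentile 0.5 among the 200 genes nearest to it in expression. In migrating excitatory neuron-like nuclei, newborn cells on their way to the cortical plate, the level was 272 against 157 CPM, a ratio of 0.575 (0.494 to 0.669). In upper-layer-like nuclei, the late-born excitatory neurons, it was 242 (229 to 257) against 178 (168 to 188) CPM. That ratio was 0.734 (0.676 to 0.796), at percentile 5.5.

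The upper-layer-like class was spread differently over its 3 clusters in the 2 libraries. Cluster 2 was the largest in the F/F-labelled and cluster 8 in the NCKO-labelled library. The Epha4 ratios of the 3 clusters differed, but their intervals overlapped. Cluster 2, with Inhba, Rorb and Bcl6 among its leading genes, had 661 F/F-labelled and 453 NCKO-labelled nuclei and an Epha4 ratio of 0.752 (0.668 to 0.846). Cluster 8, led by Met, Cav1, Fn1 and Lhx2, had 127 and 592 nuclei and a ratio of 0.924 (0.734 to 1.17). Cluster 12, led by Cntnap5c, Tshr and Ntf3, had 226 and 365 nuclei and a ratio of 0.871 (0.746 to 1.02). In clusters 8 and 12 the difference in Epha4 was thus within counting error. The ratio over the class, 0.734, was below those of all 3 clusters. In the F/F-labelled library Epha4 was at 262 CPM in cluster 2 and 151 CPM in cluster 8. Part of the class difference therefore follows the numbers of nuclei per cluster. With the clusters weighted as in the F/F-labelled library, a setting chosen after the data were seen, the ratio was 0.796.

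The Epha4 difference was not limited to late-born neurons. Intermediate progenitor-like nuclei had the highest level of the 9 populations, 854 against 530 CPM (ratio 0.621, 0.534 to 0.721), and radial glia-like nuclei had 486 against 398 CPM (0.818, 0.690 to 0.971). In radial glia-like clusters 11 and 17 the ratio was 0.760 (0.624 to 0.925) and 0.968 (0.677 to 1.39). In unnamed clusters 31, 40 and 44, which scored best as radial glia, it was 1.03, 0.909 and 0.971, each within counting error. The ratio was 0.570 in layer 5-like, 0.664 in layer 6-like, 0.600 in MGE-derived and 0.620 in CGE-derived interneuron-like nuclei, the last 2 being GABAergic cells from the medial and caudal ganglionic eminences. By cluster it was 0.467, 0.686 and 1.02 in MGE-derived clusters 3, 16 and 26, and 0.573 and 0.838 in CGE-derived clusters 13 and 39. Cluster 39, led by genes of the cell cycle, had 517 against 433 CPM, and cluster 13 had 156 against 89.4 CPM. At equal depth per nucleus the layer 5-like and layer 6-like ratios were 0.850 and 0.844. Thinning leaves fewer UMIs and both values carry no interval, so they leave open how far depth matters. The MGE-derived ratio was 0.397 with clusters from the F/F-labelled library alone. Striatal or LGE-derived neuron-like nuclei had 522 against 403 CPM (0.772, 0.720 to 0.827). Cajal-Retzius-like nuclei, the Reelin-secreting cells of the marginal zone, had 23.2 against 24.2 CPM from 6 and 15 UMIs, and astrocyte-like nuclei had 191 against 207 CPM. Subplate-like nuclei had 43.2 (27.7 to 64.4) against 57.1 (43.8 to 73.2) CPM, where no difference was detectable at this depth.

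**Figure D1:**
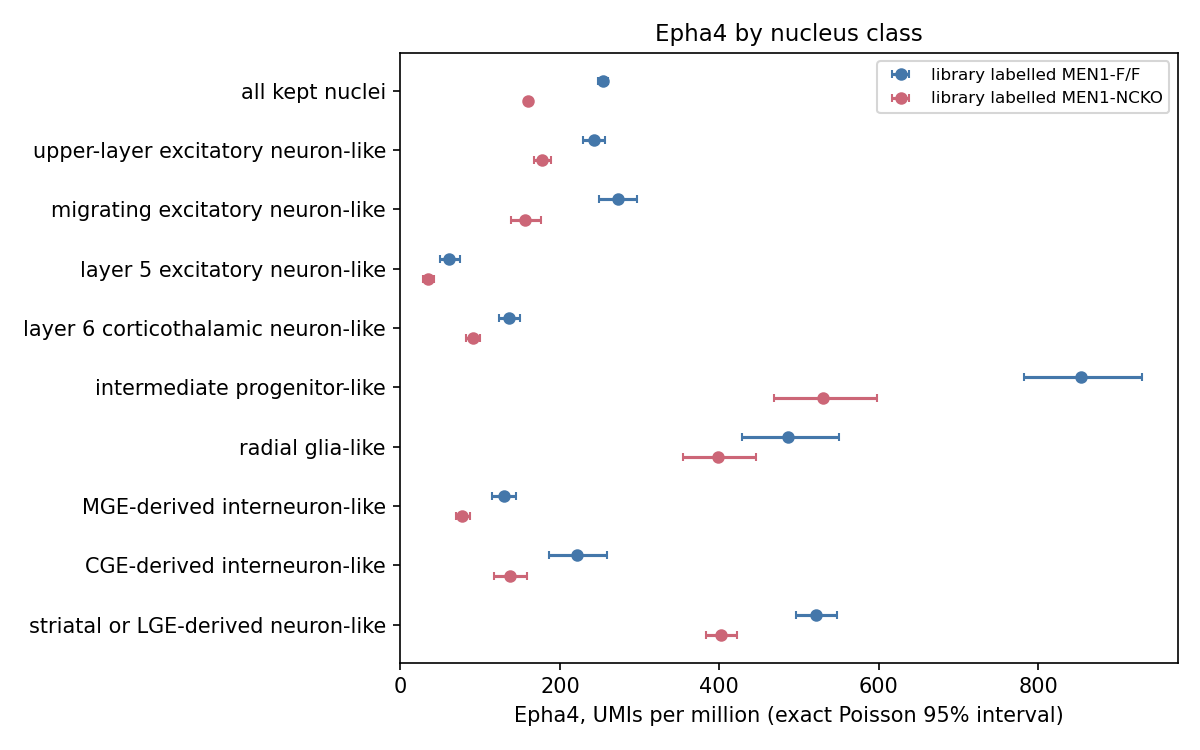
Epha4 level in CPM (horizontal axis) over all kept nuclei and in each of the 9 populations, for the library labelled MEN1-F/F (blue) and the library labelled MEN1-NCKO (red). Points are summed levels, bars are exact Poisson 95% intervals for counting error only, and the NCKO-labelled point lies below the F/F-labelled point in each population, from 530 against 854 CPM in intermediate progenitor-like to 34.7 against 60.9 CPM in layer 5-like nuclei.

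The NCKO-labelled library held smaller shares of intermediate progenitor-like, migrating and upper-layer-like nuclei and a larger share of layer 5-like nuclei. Intermediate progenitor-like nuclei, the Eomes-positive cells that divide to give neurons, made up 4.01% (3.54 to 4.53) of F/F-labelled and 2.01% (1.74 to 2.31) of NCKO-labelled nuclei. Migrating neuron-like nuclei made up 10.3% (9.51 to 11.05) against 6.76% (6.27 to 7.27). Upper-layer-like nuclei made up 16.5% (15.6 to 17.5) against 14.4% (13.7 to 15.1), and layer 5-like nuclei 3.61% (3.15 to 4.10) against 5.68% (5.23 to 6.16). These shares depended on the clustering while keeping their direction. Over 11 alternatives the ratio of the shares was 0.420 to 0.883 for upper-layer-like nuclei (0.869 as reported), 0.542 to 0.879 for migrating, 0.348 to 0.774 for intermediate progenitor-like and 1.29 to 1.58 for layer 5-like nuclei. With the 28 genes over 2-fold apart between the libraries left out of the clustering, the upper-layer ratio was 0.758.

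The shares of the other 5 populations compared differed by less than counting error as reported. Radial glia-like nuclei, the neural stem cells of the ventricular zone, made up 2.76% and 2.71%, a ratio of 0.984. It was 1.32 with all deposited barcodes, 1.36 at resolution 2 and 1.41 with genes over 2-fold apart left out of the clustering. Layer 6-like nuclei made up 9.56% and 9.34%, and MGE-derived interneuron-like nuclei 9.66% and 9.84%. CGE-derived interneuron-like nuclei made up 3.82% and 4.22%, and striatal-like nuclei 11.2% and 10.3%. The striatal-like class is named for cells outside the neocortex, so by their markers the kept nuclei were not neocortical alone. Several small classes had larger shares in the NCKO-labelled library. Subplate-like nuclei made up 1.13% against 1.68%, a ratio of 1.49 (1.13 to 1.98), and Cajal-Retzius-like nuclei 0.620% against 1.18%, a ratio of 1.91 (1.32 to 2.75). The ratio was 1.34 (1.05 to 1.70) for oligodendrocyte precursor-like nuclei (1.53% against 2.05%) and 7.34 (2.65 to 20.4) for endothelial-like nuclei, which numbered 4 against 47. Astrocyte-like nuclei made up 1.24% and 1.40%. Unnamed clusters held 22.8% and 26.4%. By their best-scoring class, their shares were 9.48% and 10.6% for migrating neurons, 4.88% and 4.55% for upper-layer neurons, 1.93% and 2.75% for layer 5, and 1.52% and 2.51% for layer 6. They were 1.55% and 1.90% for radial glia and 3.46% and 4.09% for CGE-derived interneurons.

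**Figure D2:**
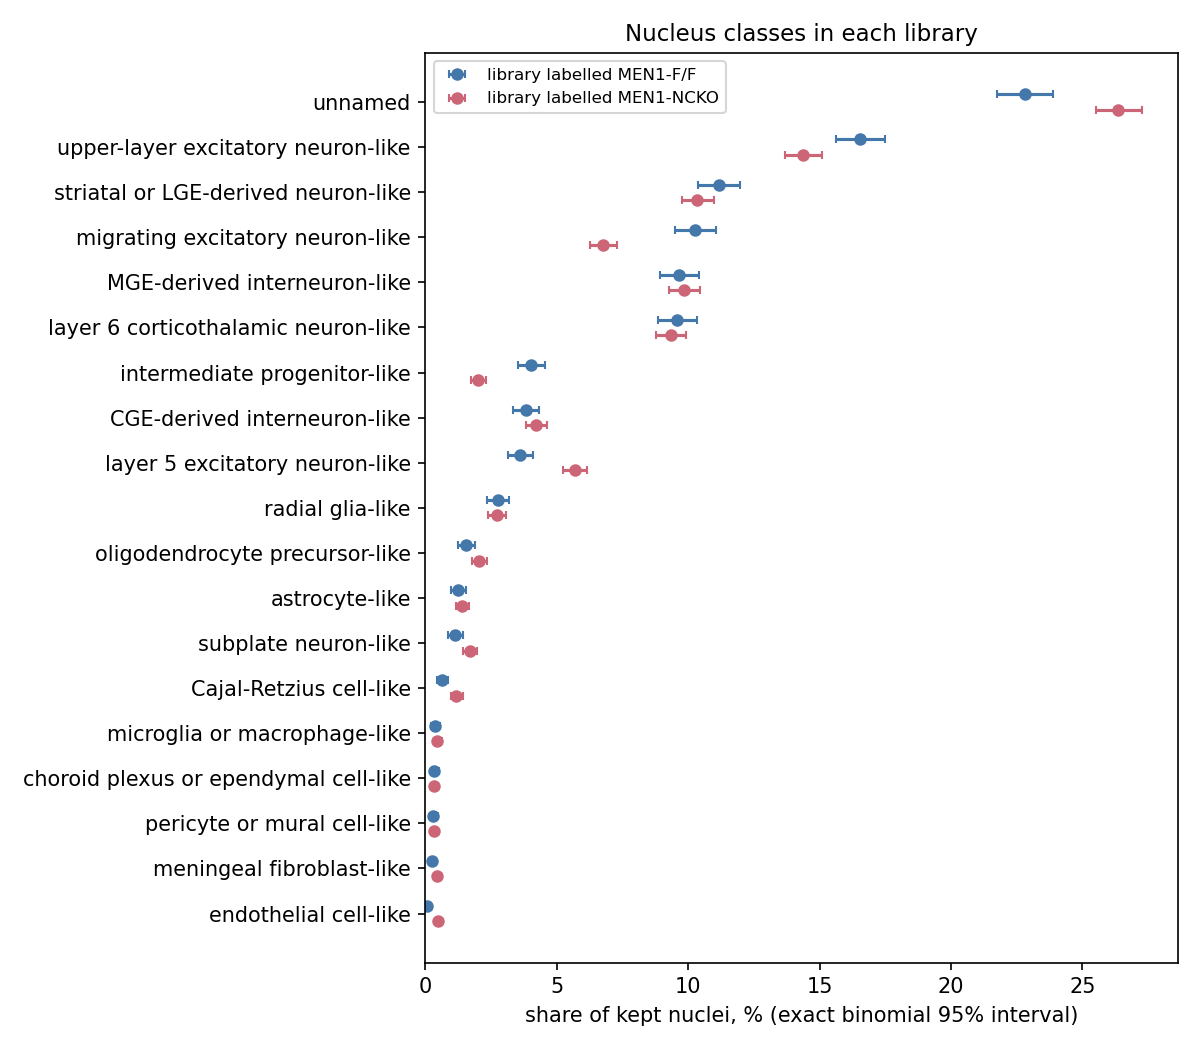
Share of kept nuclei in percent (horizontal axis) for each class, in the library labelled MEN1-F/F (blue) and the library labelled MEN1-NCKO (red). Error bars are exact binomial 95% intervals for counting error only, and migrating neuron-like (10.3% and 6.76%) and intermediate progenitor-like nuclei (4.01% and 2.01%) lie apart with the F/F-labelled library higher, and layer 5-like nuclei (3.61% and 5.68%) lie apart with the NCKO-labelled library higher.

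Late-born upper-layer-like neurons formed a smaller part of the layered excitatory neurons in the NCKO-labelled library. They were 1014 of 1890 upper-layer plus deep-layer nuclei in the F/F-labelled library, 53.7% (51.4 to 55.9). In the NCKO-labelled library they were 1410 of 3048, 46.3% (44.5 to 48.0), a difference of -7.39 percentage points (-10.3 to -4.49). The deep-layer side holds the early-born layer 5, layer 6 and subplate-like nuclei. Over 12 alternatives the difference lay between -21.7 and -8.42 points, so the value reported is the smallest of those computed. The clusters of the upper-layer-like class went different ways. Cluster 2 held 10.8% of F/F-labelled and 4.62% of NCKO-labelled kept nuclei, cluster 8 held 2.07% and 6.04%, and cluster 12 held 3.69% and 3.72%.

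Mki67 and Top2a, genes of dividing cells, were detected at similar rates in radial glia-like nuclei of both libraries, while the median of the wider G2 and M phase list there was at -0.14 (percentile 2.40), just below the random lists. At 1000 UMIs per nucleus, 35 of 169 F/F-labelled radial glia-like nuclei (20.7%) and 48 of 263 NCKO-labelled ones (18.3%) held a UMI of either gene. The difference was -2.46 points (-10.7 to 5.37). Among intermediate progenitor-like nuclei the numbers were 29 of 237 (12.2%) and 36 of 189 (19.0%), a difference of 6.81 points (-0.408 to 14.2) that was within counting error at this depth. Thinned shares come from a single random draw of UMIs at each depth, and their intervals do not cover the spread between draws. Without thinning, the shares were 31.4% and 28.9% in radial glia-like and 18.7% and 31.0% in intermediate progenitor-like nuclei. The last 2 differed by 12.3 points (3.88 to 20.65). Upper-layer-like neurons, which do not divide, gave 0.296% and 0.284% at equal depth. Their median depth was 4202.5 and 4059.5 UMIs, against 2646 and 2380 in radial glia-like and 2192 and 1963 in intermediate progenitor-like nuclei. Thinning left out 0 and 3 radial glia-like and 9 and 8 intermediate progenitor-like nuclei. Summed Mki67 and Top2a levels were 370 and 372 CPM in radial glia-like and 232 and 463 CPM in intermediate progenitor-like nuclei. The intermediate progenitor-like difference was 12.2 points (5.81 to 18.8) at 500 UMIs with no nucleus left out. At 2000 UMIs it was 21.3 points (9.09 to 33.3), with 106 of 246 F/F-labelled and 100 of 197 NCKO-labelled nuclei left out for lack of depth.

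Of the 12 genes furthest below in the NCKO-labelled library in upper-layer-like nuclei, 5 were non-coding RNAs whose nearest coding gene was Pou3f3 or Sox4, a grouping made after the values were seen. Gm29260 had 823 against 27 UMIs (log2 ratio -4.23), and Gm28175 had 1189 against 206 (-2.75). Pantr1 had 1682 against 365 (-2.51). All 3 lie on chromosome 1 with Pou3f3 as the nearest coding gene, at gaps of 756208, 391356 and 926 bp. Pou3f3 itself, a POU-domain factor of upper-layer neurons, had 417 against 197 UMIs (-1.35). 2610307P16Rik (-2.74) and A330102I10Rik (-1.76) lie on chromosome 13 at 63299 and 60686 bp from Sox4. Hexokinase 2 (Hk2) had 110 against 9 UMIs (-2.10), and Gpi1, the next enzyme of glycolysis, had 535 against 165 (-1.91). P4ha1, a subunit of collagen prolyl 4-hydroxylase, was at -1.71 and Boc, a Sonic hedgehog co-receptor, at -1.87. The RNA-binding protein gene Igf2bp1 was at -1.77 and Mir99ahg, a microRNA host gene that overlaps another annotated gene, at -2.23. Gm3739 (-1.71) belongs to a family of near-identical copies, so its count is uncertain. The sizes of these ratios depended on the setting. Gm29260 was at -5.03 with CPM + 1, -2.95 with CPM + 20 and -3.44 with no doublet removal, and Hk2 at -3.29 with CPM + 1 and -0.98 with CPM + 20. With clusters from the F/F-labelled library alone Gm28175 was at -2.08, 2610307P16Rik at -2.09, Pantr1 at -1.90, Mir99ahg at -1.61 and Gpi1 at -2.18. With CPM + 20 Igf2bp1 was at -1.18 and Boc at -1.33.

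The genes furthest above in the same nuclei were the non-coding RNA 6530403H02Rik (388 against 2626 UMIs, 2.28) and Il1rapl2, a synaptic adhesion gene (294 against 1456, 1.81). Zfp804b (1.69), Ndnf (1.67), the amino acid transporter gene Slc7a8 (1.48) and Fst, which encodes the activin-binding protein follistatin (1.47), followed. The receptor tyrosine kinase gene Alk was at 1.45, the transcription factor gene Trps1 at 1.43, the phosphodiesterase gene Pde1a at 1.40 and the nuclear receptor gene Nr4a2 at 1.29. The non-coding RNAs Gm32647 and 4930445B16Rik were at 1.38 and 1.35, the last overlapping Lrrc4c. Il1rapl2 and Zfp804b overlap coding genes too, which leaves their counts uncertain, and the same holds for St6galnac5, Sv2c, Kcnip4, Khdrbs2, Astn2, 4930578G10Rik and Otx2os1 among the genes named in other populations. Fst is a leading gene of cluster 8, which held 127 and 592 nuclei. With the 3 clusters weighted as in the F/F-labelled library, a setting chosen after the data were seen, Fst was at 0.83, Pde1a at 0.86 and Ndnf at 0.95. Several of the higher genes were also far smaller under other filters or clusters. Zfp804b was at 0.23, Fst at 0.59, Trps1 at 0.82, Pde1a at 0.81 and Nr4a2 at 0.82 with no doublet removal. With clusters drawn from the F/F-labelled library alone, Zfp804b was at 0.45, Il1rapl2 at 0.75, Pde1a at 0.65 and Gm32647 at 0.25, while 4930445B16Rik was at 1.71. Of the 24 genes, 13 were named again in that setting, 17 with no doublet removal and 19 with all deposited barcodes.

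Among the fixed lists, genes of glycolysis and hypoxia stood lowest in upper-layer-like nuclei. All 15 measured members were lower in the NCKO-labelled library, with a median log2 ratio of -0.76, at percentile 0 of the random lists. The size of this median depended on the pseudocount, at -1.01 with CPM + 1 and -0.40 with CPM + 20. Examples are the enzyme genes Eno1 (-1.03), Ldha (-1.11) and Pgk1 (-0.76), the kinase gene Pdk1 (-1.18), the angiogenic factor gene Vegfa (509 against 313 UMIs, -1.04) and Bnip3 (-1.07). The medians in clusters 2, 8 and 12 were -0.77, -0.48 and -0.84. The median was below 0 in each of the other 8 populations as well, from -1.06 in radial glia-like and -0.95 in striatal-like to -0.27 in CGE-derived interneuron-like nuclei. In the last it was at percentile 6.88, within the range of random lists. It was -0.85 in MGE-derived interneuron-like, -0.83 in migrating, -0.82 in intermediate progenitor-like, -0.58 in layer 6-like and -0.55 in layer 5-like nuclei.

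Upper-layer transcription factors were lower together. Of 12 members, 11 were below 0 in upper-layer-like nuclei, with a median of -0.39 at percentile 0. Cux2 (3167 against 1622 UMIs, -1.36), Cux1 (4051 against 2369, -1.17) and Pou3f2 (631 against 364, -1.13) were among the lowest. Bhlhe22 was at 0.01. The list shares 8 genes with the markers that named the class, so its members also took part in deciding which nuclei are compared. The median was -0.46, -0.21 and -0.31 in clusters 2, 8 and 12, and single genes varied among them. Cux2 was at -1.47, -0.59 and -0.62, Cux1 at -1.06, -0.33 and -0.69, Pou3f2 at -1.24, 0.06 and -0.95, and Rorb, at -0.70 over the class, at -0.60, 0.06 and 0.66. In migrating neuron-like nuclei the median was -0.28 at percentile 0.28. Gliogenic factors were also lower, with 6 of 6 measured members below 0 and a median of -0.32 at percentile 0.5. These included Nfia (1109 against 507, -1.48) and Zbtb20 (738 against 429, -1.13), which both act in neurons as well.

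Guidance and adhesion genes differed by family. Of 10 Eph receptors measured in upper-layer-like nuclei, 6 were below 0, with a median of -0.18 at percentile 2.32. Within clusters 2, 8 and 12 the list was at -0.27 (percentile 1.06), -0.10 (19.1) and 0.06 (68.2), so it lay below the random lists in cluster 2 alone. Epha4 was at -0.44 and Ephb6 at -0.45, while Epha7 was at 0.30 and Epha6 at 0.72. Epha6 was at -0.21, 0.08 and -0.53 within clusters 2, 8 and 12, so its value over the class follows their numbers of nuclei. Ephrins had a median of -0.0020 at percentile 47.2. The Slit, Robo and netrin list was at -0.23 (percentile 0.4), with Unc5d at -1.19, Robo2 at -0.49 and Slit3 at 1.06, and with clusters drawn from the F/F-labelled library alone its median was 0.028. In clusters 2, 8 and 12 it was at -0.08 (23.2), -0.23 (0.98) and -0.07 (19.9). In clusters 2 and 8 Unc5d was at -0.70 and -1.30, Robo2 at -0.25 and -0.23 and Slit3 at 0.14 and 0.23. Semaphorins, plexins and neuropilins were at 0.18 (99.5), with Nrp2 at 1.13, but at 0.01 (56.3), -0.18 (2.82) and 0.17 (93.1) in clusters 2, 8 and 12 and at 0.012 with all deposited barcodes. Protocadherins and cadherins were at 0.25 (percentile 100), with 3 of 20 below 0, and at 0.18 (99.8), 0.05 (85.3) and 0.25 (99.8) in the 3 clusters. Cdh13 had 4072 against 9400 UMIs (0.79), and Pcdh10 was at 0.71. The Reelin pathway and radial migration list was at 0.10 (96.2), with 3 of 20 below 0.

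Excitatory synapse genes had a median of 0.24 (percentile 99.99) in upper-layer-like nuclei. In clusters 2, 8 and 12 it was 0.23 (99.99), 0.08 (94.7) and 0.05 (71.0), and it was 0.13 with no doublet removal. Members went both ways, with the glutamate receptor genes Grm5 at 0.55 and Gria3 at 0.64 and the vesicular transporter gene Slc17a6 at -1.34. Cholesterol synthesis genes were at 0.21 (99.8) with 0 of 14 below 0, and at 0.24 (99.9), 0.22 (98.8) and 0.33 (percentile 99.96) in the 3 clusters, above the random lists in each. Ribosomal protein genes were at 0.12 (98.2), and at 0.06, 0.03 and 0.21 in the clusters, above the random lists in cluster 12 alone. Mitochondrially encoded genes were at 0.37 (percentile 100), and at 0.40, 0.13 and 0.43, within the random lists in cluster 8. Immature neuron genes were at 0.17 (99.4), among them Tubb3 (0.37) and Stmn1 (0.28), with Igfbpl1 at -1.56, and at 0.13, 0.10 and 0.14 in the clusters, above the random lists in cluster 2 alone. In clusters 2 and 8, 4 and 5 of the 12 measured members of this list were below 0. Among these were Sox4 (-0.54 and -0.46), Sox11 (-0.46 and -0.20) and Igfbpl1 (-1.59 and -1.40). The menin and MLL complex list was at 0.16 (97.8), with Kmt2b at 0.31 and Kmt2a at -0.11, but within the random lists in each cluster (0.09, -0.10 and 0.18). Stress lists rest on few members. The integrated stress response list was at 0.28 (98.1, 4 members), with the chaperone gene Hspa5 at 0.43, and the immediate early and heat shock list was at 0.32 (97.6, 3 members). Both were within the random lists in the clusters with 3 or more measured members, the first at 0.39 and 0.27 in clusters 2 and 8 and the second at 0.21 in cluster 2.

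The remaining lists lay within the central range of random lists in upper-layer-like nuclei. Their medians were 0.06 for deep-layer transcription factors (0.51 with no doublet removal), -0.01 for voltage-gated channels, -0.0033 for presynaptic release and adhesion, and -0.11 for inhibitory synapse. They were -0.16 for the Notch pathway, 0.0017 for the Wnt pathway, -0.04 for S phase, 0.03 for G2 and M phase and 0.04 for the p53 pathway and apoptosis. Menin-linked cell cycle inhibitors and homeobox genes, which menin is known to regulate in endocrine and blood cells, were at -0.08 (percentile 25.2). Of these, Cdkn1b was at -0.31 (59 against 57 UMIs) and Cdkn2c did not reach the minimum of 50 UMIs.

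**Figure D3:**
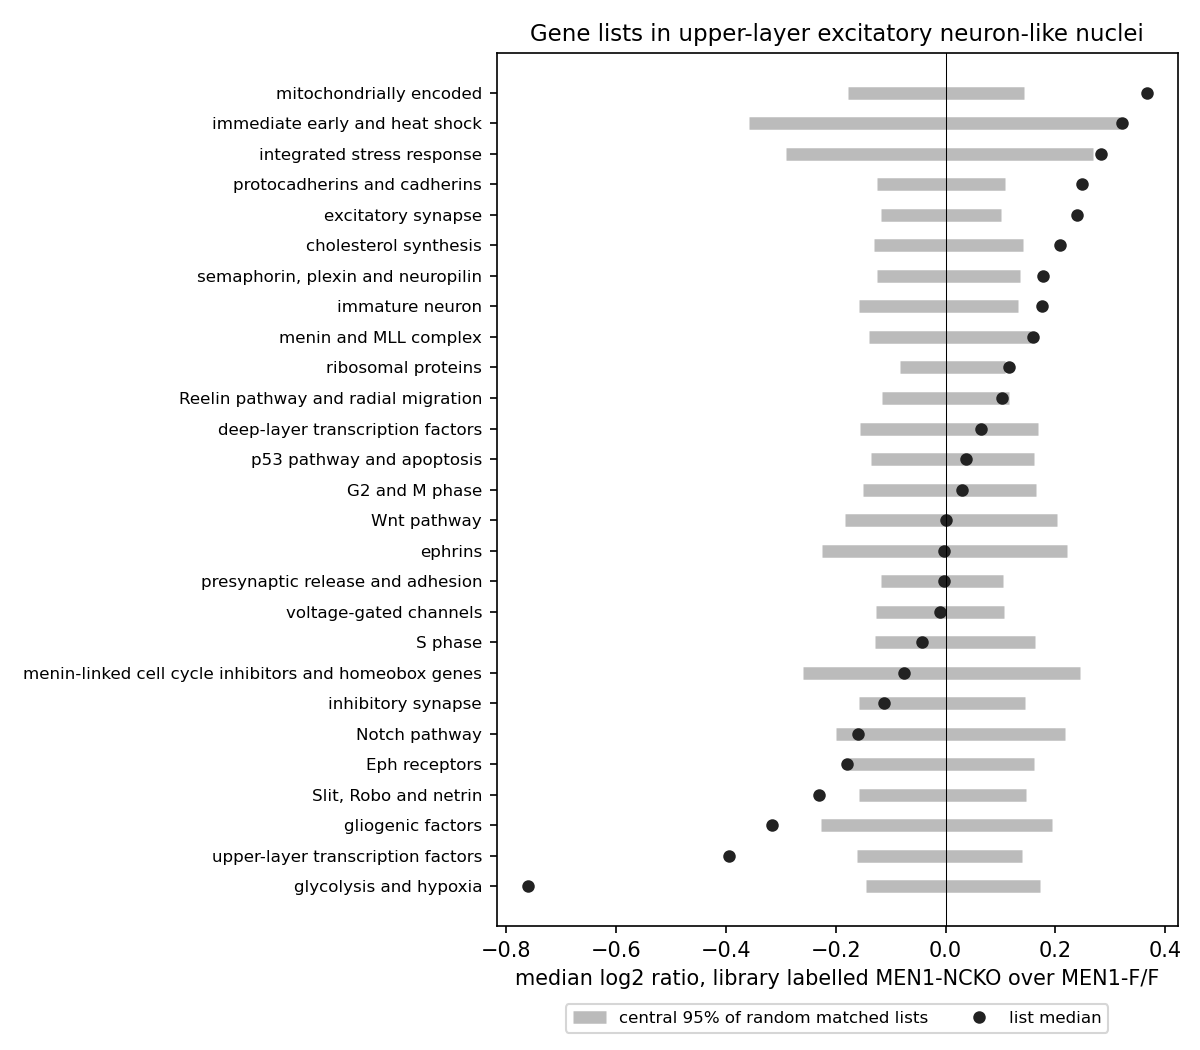
Median log2 ratio of each gene list (points, horizontal axis, NCKO-labelled over F/F-labelled library) in upper-layer-like nuclei, with the central 95% of 10000 random lists matched in size and expression (grey bars). Glycolysis and hypoxia (-0.76) and upper-layer transcription factors (-0.39) lie furthest below 0, and mitochondrially encoded genes (0.37) furthest above.

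In radial glia-like nuclei the growth factor adaptor gene Grb10, which is imprinted, had 103 UMIs in the F/F-labelled and 8 in the NCKO-labelled library (log2 ratio -3.68). Other genes far below were Gm28175 (-1.76), Vegfa (-1.55), 4930578G10Rik (-1.51), P4ha1 (-1.27), Lockd (-1.27), the guidance ligand gene Slit2 (-1.21) and Fam210b (-1.15). Gm19522 (-1.28) overlaps Zbtb20 on annotation as an antisense gene. Lingo2 (-1.70), Adarb2 (-1.60) and Sorbs2 (-1.17) turned positive under other filters or clusters, Lingo2 reaching 1.81 with all deposited barcodes and Adarb2 1.32 with no doublet removal. The genes named in this class depended on the processing, since of these 24 only 7 were named again with all deposited barcodes, 12 with no doublet removal, 2 with no count minimum and 7 with clusters from the F/F-labelled library alone. With all deposited barcodes Vegfa was at -0.73 and Lockd at -2.22, and with no doublet removal Slit2 was at -0.44. Genes far above were Sgcz (12 against 122 UMIs, 2.59), Agbl1 (2.01), the neurexin-family gene Cntnap2 (1.71), Khdrbs2 (1.68), Astn2 (1.46), Prex2 (1.43), Dlgap2 (1.43), Rgs6 (1.38), the GABA receptor subunit gene Gabrg3 (1.32), the netrin receptor gene Unc5c (1.23), Zbtb7c (1.20) and Sgcd (1.18). Of these, Dlgap2 was at 0.40 and Unc5c at 0.64 with all deposited barcodes, and Sgcz was at 1.48, Rgs6 at 0.55 and Gabrg3 at 0.80 with clusters from the F/F-labelled library alone. The class is held by clusters 11 and 17 in both libraries. In the doublet check 47.3% of the added doublets were among the scores removed, and what remaining doublets add to this class was not tested.

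Gene lists in radial glia-like nuclei repeated the low glycolysis and hypoxia genes, with 6 of 6 below 0 and Hk2 at -1.92, and a median of -0.66 with all deposited barcodes. Protocadherins and cadherins were at 0.27 (99.7; 0.58 with all deposited barcodes), and immature neuron genes at 0.32 (99.8), although radial glia are not neurons. G2 and M phase genes were at -0.14 (percentile 2.40), with 22 of 34 below 0, and at -0.34 with clusters from the F/F-labelled library alone. The ephrin median of 0.65 rested on 3 members, Efna5 (13 against 66 UMIs, 1.65), Efnb2 (0.65) and Efnb1 (-0.14), and was -0.19 with no count minimum. In intermediate progenitor-like nuclei G2 and M phase genes were higher, with 4 of 29 below 0, a median of 0.37 (99.9), Mki67 at 1.31 and Ect2 at 1.92. The libraries differed in the clusters that hold this class. Cluster 23, led by Eomes, had 140 of the 246 F/F-labelled and 78 of the 197 NCKO-labelled nuclei, while clusters 38 and 41, led by genes of the cell cycle, had 63 and 15 against 71 and 16. Ribosomal protein genes there were at 0.60, and another scaling moved the median of all genes in this class by -0.11.

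Some genes recurred among those named in several populations, with all kept nuclei counted as one of them. Gm29260 was among the lowest in 7, with 2323 against 436 UMIs in migrating neuron-like (-2.26), -2.71 in MGE-derived interneuron-like and -2.38 in striatal-like nuclei. Gm3739 recurred in 7, Gpi1 in 6, Gm28175 in 5 and 2610307P16Rik in 4, with 1475 against 154 UMIs in layer 6-like nuclei (-3.59). In migrating neuron-like nuclei the transcription factor gene Creb5 (-2.53), Gm44593 at 1956 bp from Pou3f4 (-2.28) and Mpped2 (-2.14) were among the lowest. Ebf1 (2.47), Hs3st5 (2.20) and Sv2c (1.44) were highest. In layer 5-like nuclei the mineralocorticoid receptor gene Nr3c2 was highest (2.05), and St6galnac5 (-1.88) and the neurotensin gene Nts (-1.73) were among the lowest. In layer 6-like nuclei Alk (1.94), Vwc2 (1.78) and Il1rapl2 (1.77) were highest.

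In MGE-derived interneuron-like nuclei 6530403H02Rik (2.38) and Kcnip4 (1230 against 5701 UMIs) were among the highest and Ebf1 (-1.73) among the lowest. In CGE-derived interneuron-like nuclei Kcnip4 (2.43), Tafa2 (2.32) and Nxph1 (2.25) were highest and Zfp804b (-2.39) was lowest. In striatal-like nuclei Unc13c (1.37) was among the highest and Igf2bp1 (-2.24) among the lowest. Over all nuclei the endothelial genes Mmrn2 (1.34), Cldn5 (1.13) and Mecom (1.09) were among the highest, beside the 4 and 47 endothelial-like nuclei. The choroid plexus gene Ttr was lowest (1472 against 350 UMIs, -2.16), followed among others by Otx2os1 (-1.68), with 21 and 33 choroid plexus or ependymal-like nuclei, of which 28.6% and 12.1% held a UMI of Ttr.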

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

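The tests of cluster and class composition, free RNA, cytoplasmic RNA and a later stage were chosen after the results were seen, and the test of low oxygen after the list was seen but before the values of its own genes.

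Xist and the Y-linked genes stand outside the comparisons, and both libraries have the RNA of the inactive X chromosome at a high level. Xist was at 2551 CPM in the F/F-labelled and 2652 CPM in the NCKO-labelled library, with a UMI in 99.1% (98.9 to 99.3) and 95.9% (95.4 to 96.2) of nuclei. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 19 and 23 UMIs, 0.709 and 0.555 CPM. In upper-layer-like nuclei Xist had a log2 ratio of 0.10 and its antisense gene Tsix -0.01. The protocol in the labels speaks of male mice without giving the sex of the embryos.

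Epha4 was lower over all nuclei (ratio 0.631) and in each of the 9 populations compared. A shift in the clusters that make up the libraries does not account for all of it, since with each of 45 clusters weighted as in the F/F-labelled library the ratio was 0.719 (0.695 to 0.745). RNA free in the suspension would give a similar gap in each class, but the gap in Cajal-Retzius-like nuclei was -0.952 CPM (-22.4 to 28.3) against 93.9 CPM over all nuclei. Within 5 bins of a maturity score over migrating and upper-layer-like nuclei the weighted ratio was 0.691 (0.644 to 0.741), with 0.596 to 0.834 in single bins. Both libraries were spread about evenly over the bins, with 325 and 419 nuclei in the first and 317 and 426 in the last. Weighting by these bins could thus change little, and a shift in maturity that the score misses was not tested. A lower Epha4 level tied to genotype is a hypothesis that remains, and embryo, litter and library differences remain open beside it as untested.

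Genes of glycolysis and hypoxia were lower in the NCKO-labelled library, and 9 of the 9 populations had a list median below -0.1, which a shift in class composition alone would not give. Less cytoplasmic RNA in that library would lower ribosomal protein genes too, but their median over all nuclei was 0.21. A candidate explanation is a low-oxygen response in the F/F-labelled tissue. It needs other genes induced by low oxygen to be lower too, and of 13 such genes outside the list, from Plod2 at -0.68 to Pfkfb4 at 0.08, 12 were below 0, with a median of -0.30 that lies below the random lists (-0.09 to 0.15) but only just past the -0.3 set as the bound. The time from dissection to freezing is not given in the sources used here, and each label has 1 library. Handling, genotype, embryo, litter, stage and region therefore cannot be separated as origins of such a response.

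Intermediate progenitor-like and migrating neuron-like nuclei had smaller shares in the NCKO-labelled library, which might come from a later stage or from another part of the neocortex. The immature neuron list had a median below 0 in 0 of 7 neuronal populations, where a later stage would lower it. In 5 of these 7 it was below the ribosomal protein median. Its members also went both ways, with Sox4, Sox11 and Igfbpl1 lower in upper-layer-like clusters 2 and 8. A later stage thus cannot be told apart from a genotype difference. In radial glia-like nuclei the caudal genes Nr2f1 and Emx2 less the rostral genes Sp8 and Pax6 gave -0.62 (-1.14 to -0.0035), a value that rests on Sp8 with 0 and 5 UMIs. Without Sp8 it was -0.23 (-0.77 to 0.28), and these few UMIs leave a difference in region open.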

How the results depend on the processing

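The settings chosen after the data were seen were centring, the other naming rules, the migrating and upper-layer classes combined, and clusters weighted as in the F/F-labelled library. No paired analysis was possible because each label has 1 library. The ratio of Epha4 lay between 0.622 and 0.631 over all nuclei in 5 alternatives. This range leaves out the weighting of the 45 clusters as in the F/F-labelled library, which gave 0.719. The ratio over all nuclei does not depend on the clustering, so few settings could move it. It lay between 0.606 and 0.796 in upper-layer-like nuclei in 11 alternatives and between 0.502 and 0.684 in migrating neuron-like nuclei in 10. Of the values under alternatives, 161 class shares lay within the counting interval and 31 outside it, and for Epha4 88 and 10. Among the class shares outside it, the radial glia-like ratio, 0.984 as reported, crossed 1 to 1.32, 1.36 and 1.41. For Men1 56 lay within, 2 moved and 1 was counted as reversed, and for gene ratios 307, 88 and 5. Of the 2 that moved, Men1 in migrating neuron-like nuclei also crossed 1, from 1.29 to 0.579 with no doublet removal. For gene lists, 397 moved by less than 0.5 of the width of the central range of random lists, 23 by more and 3 were counted as reversed. The 23 hold changes of sign too. In radial glia-like nuclei the Slit, Robo and netrin list was at 0.41 with all deposited barcodes and -0.11 with no count minimum. Where no cause is named, the cause was not tested.

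At 1000 UMIs per nucleus the ratio of Men1 was 1.08 over all nuclei (1.32 as reported) and 0.853 in layer 6-like nuclei (1.65), on fewer UMIs by construction. That of Epha4 was 0.606 in upper-layer-like (0.734) and 0.684 in migrating neuron-like nuclei (0.575). With clusters weighted as in the F/F-labelled library it was 0.796 in upper-layer-like nuclei. At 2000 UMIs the difference in cycling intermediate progenitor-like nuclei was 21.3 points (6.81), from 140 and 97 nuclei deep enough. The glycolysis and hypoxia median in upper-layer-like nuclei was -1.01 with CPM + 1 and -0.40 with CPM + 20 (-0.76), because the pseudocount sets how far low genes are drawn to 0. With no count minimum the ephrin median in radial glia-like nuclei was -0.19 (0.65).

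The reported ratios of shares were 0.501 for intermediate progenitor-like, 0.659 for migrating, 0.869 for upper-layer-like and 1.58 for layer 5-like nuclei, with a balance of upper to deep layers of -7.39 points. With all deposited barcodes the first 3 were 0.774, 0.778 and 0.757 and the balance -12.4 points, and in radial glia-like nuclei Lingo2 was at 1.81 (-1.70) and Sorbs2 at 0.11 (-1.17). With no doublet removal the 3 ratios were 0.607, 0.542 and 0.696 and the balance -14.6 points, with Lingo2 at 0.82 and Adarb2 at 1.32 (-1.60). Without genes over 2-fold apart the ratios were 0.742, 0.736 and 0.758 and the balance -10.5 points.

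With clusters from the F/F-labelled library alone, intermediate progenitor-like nuclei had a ratio of 0.754, upper-layer-like nuclei 0.608 and the balance was -16.2 points. There, 13 of the 24 named upper-layer genes were named again, the Slit, Robo and netrin median was 0.028 (-0.23) and the ribosomal protein median 0.26 (0.12). In radial glia-like nuclei the ephrin median was -0.0030 and Lingo2 was at 0.74. At resolution 0.5 the ratios for intermediate progenitor-like and upper-layer-like nuclei were 0.702 and 0.774, with a balance of -12.0 points. At resolution 2 migrating neuron-like nuclei had 0.791, upper-layer-like nuclei 0.420 and the balance was -21.7 points. With centred genes these were 0.789, 0.745 and -13.1 points. With at least 1000 genes per nucleus upper-layer-like nuclei had 0.657 and the balance was -16.8 points. Without splitting, intermediate progenitor-like nuclei had 0.348 and layer 5-like nuclei 1.29. Both values were the same with markers scored against all other nuclei, where upper-layer-like nuclei had 0.428 and the balance was -21.3 points. With every cluster given its best-scoring class, migrating neuron-like nuclei had 0.879.

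Depth limits Men1, which had 12 and 6 UMIs in radial glia-like nuclei.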

Other observations

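The genes described here lie outside the comparisons above or were grouped after their values were seen, and no explanation was tested for them.

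RNA of blood and choroid plexus differed between the libraries in opposite directions. The haemoglobin gene Hbb-bs was at 21.3 CPM in the F/F-labelled and 42.7 CPM in the NCKO-labelled library over all nuclei, and at 14.4 and 30.0 CPM in upper-layer-like nuclei. Hba-a1 was at 9.66 and 16.4 CPM over all nuclei. The transthyretin gene Ttr, made by the choroid plexus, was at 54.9 and 8.44 CPM over all nuclei and at 13.2 and 3.05 CPM in upper-layer-like nuclei. Of the 21 and 33 choroid plexus or ependymal-like nuclei, 28.6% and 12.1% held a UMI of Ttr, so its level in this class rests on a few nuclei and is not compared.

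Cholesterol synthesis genes were higher over all nuclei with 0 of 14 below 0 and a median of 0.25, and the median reached 0.74 in CGE-derived and 0.45 in MGE-derived interneuron-like nuclei. In radial glia-like nuclei it was -0.05. In intermediate progenitor-like nuclei the Reelin pathway and radial migration list was at 0.36, with 11 against 69 UMIs of Reln (2.64). An unnamed cluster led by Gm32647, Zbtb20, Slit3 and Nrp2 among others had an Epha4 level of 1137 CPM in the F/F-labelled and 746 CPM in the NCKO-labelled library, from 103 and 135 nuclei.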
